A study of Homo sapiens with 6 samples.

How the data were processed

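RNA of LN-229 cells, an established human glioblastoma line, was sequenced in 6 libraries: 3 of a control and 3 labelled sh-JMJD1C, by its usual reading a short hairpin RNA directed against the JMJD1C transcript. Per the labels' protocols, RNA was extracted with TRIzol and made into libraries with a VAHTS Universal V6 kit, and the design text states that the RNA was enriched for the nucleus and depleted of ribosomal RNA. The labels do not say whether libraries of a group came from separate cultures, so every p-value measures only the spread between these libraries.

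The authors deposited a table of FPKM (fragments scaled to gene length and to the library total) per library, with 58174 Ensembl genes in each. Per the file headers, the columns hold FPKM computed on rising shares of a library's reads, and the last column, used here, holds the full library. Bowtie 0.12.2 and the genome build hg38 are named in the submitters' processing notes, with no role given. The counting tool, its annotation and its use of strand are not given in the sources used here. Gene names, biotypes and coordinates (hg38, counted from 1) were looked up by gene ID: 57392 IDs had a symbol in the gene name table and 57836 were in GENCODE release 29.

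The deposited FPKM of low genes are whole multiples of what 1 read is worth, so whole reads were recovered per gene from its FPKM, its length and the library total that makes low values whole. Where the annotated length of a gene did not make its values whole, the smallest length that did was taken, over all columns. Of the recovered values under 1000 reads, 100.0% were whole within 0.05 of a read, in part by that choice of length, and the recovered reads of each library added up to 100% of the total found from its low genes. For 27464 of the 29280 genes above 0 in a library (93.8%), the length that the authors divided by equals the sum of the lengths of all annotated transcripts of the gene in GENCODE release 29, and the same held for 90.1% of the 16506 such genes with several transcripts. The deposited FPKM of a gene with many transcripts is therefore low against that of a gene with few, which leaves comparisons of the same gene between libraries as they are. In simulated tables, with the lengths of genes with several transcripts withheld, the recovery returned the exact reads of 99.0% of 5900 detected genes and of 98.2% of 3065 genes with at least 60 reads.

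The recovered library totals were 544442, 2004255 and 2960456 reads for control 1 to 3 and 1676755, 1919675 and 1660561 reads for sh-JMJD1C 1 to 3. A count of 0 allows up to 3 reads, which is 5.51, 1.50 and 1.01 RPM (reads scaled to a common library total) in control 1 to 3 and 1.79, 1.56 and 1.81 in sh-JMJD1C 1 to 3. Intervals for reads of single libraries are exact (Clopper-Pearson) binomial intervals at 95%. Intervals and floors cover counting error only, since no molecular identifiers are described.

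The following choices were fixed before the data were examined. Each library's FPKM was divided by a median-ratio factor from genes with a mean FPKM of at least 1 and a value above 0 in all libraries, and genes with a mean FPKM of at least 0.5 were tested (18383 genes). The values log2(scaled FPKM + 0.5) were fitted with limma 3.58.1 in R 4.3.3 on the group alone, with the trend option of its empirical Bayes step, a two-sided test and Benjamini-Hochberg adjustment at 0.05. Fold changes of that fit are on the log2(value + 0.5) scale, which understates the change of low genes. JMJD1C was also compared with a two-sided exact permutation test, for which 3 libraries against 3 cannot go below p = 0.10. The 33 gene lists, described with their results below, were fixed as well and tested with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 29 lists with at least 5 measured members. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run beside it. The genes to name were JMJD1C and, in each direction, up to 12 genes with the largest fold change among those with adjusted p below 0.05, a mean FPKM of at least 1 and no overlap between the groups, leaving out clone names, pseudogenes and small RNAs.

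A second fit was chosen after seeing the data, once whole reads could be recovered. The reads of 11877 genes with at least 60 reads over the 6 libraries were scaled by median-ratio factors over genes with a mean of at least 20 reads and fitted with limma-voom. The same naming rule was then applied to the genes of this fit outside the histone genes, also after seeing the data. A version of this fit removed from each library a lowess trend (span 0.3) of the log2 fold over transcript length, taken as the longest annotated transcript, and another removed the trend over GC content as well. Levels from this fit are scaled RPM. Where a gene has 0 reads in a group, the fold is a lower bound against 3 reads over the group. Where it has 1 to 3 reads in a group, the ratio of summed scaled reads is given with its exact counting interval.

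Both fits were tested on simulated counts drawn from the means and totals of these libraries with a dispersion of 0.15, in 3 draws, each with 100 genes changed by each fold. The FPKM fit, on 18332 genes, recovered 2.67% of 4-fold and 20.7% of 8-fold changes, with 13.3 false calls per draw. The fit on reads, on 11831 genes, recovered 59.0% and 87.7%, with 5.33 false calls per draw. These rates hold for draws at that dispersion, which is not given here as an estimate from these libraries. Trends shared by many genes of a library, such as that over transcript length, are not described as part of the draws. The rates therefore do not give the power or the false calls of either fit on the real libraries.

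Alternatives fixed with these choices were other pseudocounts, other filters on low values, FPKM as deposited, quantile normalization, protein-coding genes only, empirical Bayes without trend, array weights, a replicate block and leaving out each library in turn. Alternatives chosen after seeing the data were every fit on reads and the removal of both libraries numbered 1. The columns computed on part of a library were used only to recover reads. Sequence reads and alignments were not analysed here, and some results of single genes are not reported here. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for the recovery and the plots.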

Results

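Nuclear-enriched RNA of LN-229 glioblastoma cells was compared between 3 control libraries and 3 sh-JMJD1C libraries, to find genes whose level depends on JMJD1C, a member of the JmjC-domain family of histone demethylases. The libraries held between 544442 and 2960456 reads, and control 1 was the smallest. Between 15926 and 25734 genes were above 0 per library. Log2 levels correlated across genes at 0.642 to 0.70 between control libraries, 0.732 to 0.847 between sh-JMJD1C libraries and 0.589 to 0.793 between groups. The first principal component held 38.5% of the variance and placed control libraries at -117.9 to -43.9 and sh-JMJD1C libraries at 11.1 to 110.3, with sh-JMJD1C 1 nearest to the controls.

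The libraries also differed in their RNA classes. In control 1, 25.03% of reads fell on a single gene, ENSG00000281181, against 1.32% in control 2. The gene is annotated as a long non-coding RNA at chromosome 21, 8437629 to 8438551, and which RNA its reads came from was not tested. Transcripts of the RN7SL genes, the RNA of the signal recognition particle, took 0.378%, 0.590% and 1.77% of reads in control 1 to 3 and 1.18%, 15.7% and 18.5% in sh-JMJD1C 1 to 3. Mitochondrial genes took 7.04%, 8.70% and 2.93% in the controls and 12.6%, 1.33% and 1.70% in sh-JMJD1C 1 to 3. MALAT1, a long non-coding RNA retained in the nucleus, took 1.73%, 1.25% and 2.40% in the controls and 0.292%, 0.0915% and 0.185% in the sh-JMJD1C libraries. Libraries control 1 and sh-JMJD1C 1 stand apart from the others of their groups in depth or in these shares, so counts are also given without both.

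JMJD1C (ENSG00000171988, chromosome 10, 63167221 to 63521850, minus strand) was lower in every sh-JMJD1C library than in every control library. Its scaled FPKM was 3.48 ± 1.09 in the controls and 0.641 ± 0.386 in the sh-JMJD1C libraries (mean ± SD, n = 3 each, as for all levels below), 18.4% of the control mean. Replication-dependent histone genes, which supply the core and linker histones of new chromatin in S phase, were higher in the sh-JMJD1C libraries, with a median log2 fold change of 3.47 over 61 measured genes (limma camera adjusted p = 1.58e-38, and adjusted p = 0.399 with an estimated correlation). Among them, H2BC3, which encodes an H2B histone, went from 15.9 ± 6.32 to 845 ± 493 scaled FPKM. Genes of the unfolded protein response, which relieves stress of the endoplasmic reticulum, and of the amino acid response were tested as 1 list. That list was lower, with a median of -0.62 over 36 genes (camera adjusted p = 5.30e-05, and adjusted p = 0.378 with an estimated correlation). Among its genes was DNAJB9, a co-chaperone of the endoplasmic reticulum, which went from 8.61 ± 0.931 to 1.03 ± 0.274 scaled FPKM. NIBAN1, a stress-induced regulator of translation, went from 16.3 ± 2.71 to 1.06 ± 0.782.

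Per library, JMJD1C had 145 (exact 95% binomial interval 115 to 181), 114 (99.9 to 130) and 236 (219 to 254) RPM in control 1 to 3. It had 45.3 (35.7 to 56.7), 8.33 (4.76 to 13.5) and 24.1 (17.2 to 32.8) in sh-JMJD1C 1 to 3, from 76, 16 and 40 reads. The planned limma fit gave a log2 fold change of -1.82 (SE 0.41) with an adjusted p of 0.118, which is not past the threshold, and the exact permutation test gave p = 0.10, the smallest it allows. Over protein-coding genes alone, the adjusted p of the same limma test was 0.0213. On recovered reads, limma-voom gave -2.49 (SE 0.51), 5.64-fold lower, with an adjusted p of 0.0253, and -1.75 (SE 0.42) with an adjusted p of 0.0463 once the trend over transcript length was removed. With the trend over GC content removed as well, the JMJD1C level on recovered reads was -1.20 with an adjusted p of 0.0574, which is not past the threshold. The call on reads was lost without control 1 (adjusted p = 0.104), control 3 (0.0906), sh-JMJD1C 2 (0.113) or sh-JMJD1C 3 (0.055), and held without both libraries numbered 1 (log2 fold change -2.83, adjusted p = 0.0281).

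**Figure D1:**
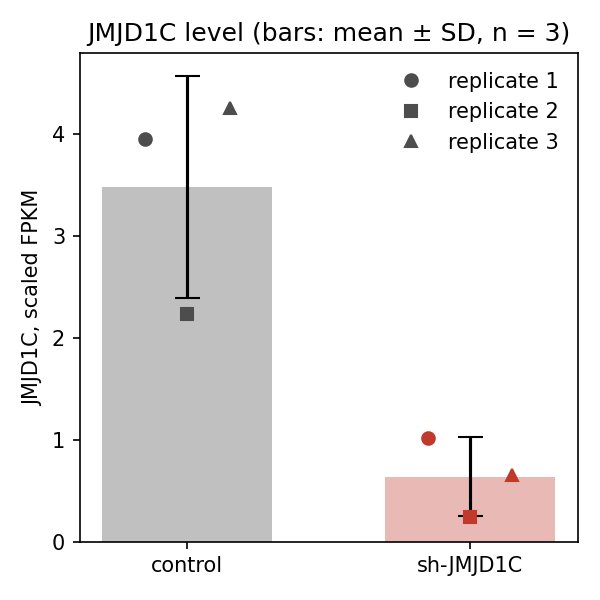
JMJD1C level in scaled FPKM (vertical axis, from 0) in the control and sh-JMJD1C groups, with bars for the mean, error bars for the SD of 3 libraries and symbols for single libraries. All 3 sh-JMJD1C libraries lie below all 3 controls.

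The planned limma fit called 34 of 18383 genes, 11 higher and 23 lower in the sh-JMJD1C libraries, and 3654 genes had an unadjusted p under 0.05. Of the 34 genes, 9 are protein-coding, 22 rest on fewer than 60 reads over all libraries and 23 have 0 reads in a group. Of the 34, 12 had enough reads for the second fit, which called all 12. Without both libraries numbered 1, the planned fit called 0 genes, with 4206 at an unadjusted p under 0.05, and limma-voom on reads called 1007. Leaving out sh-JMJD1C 1 alone gave 488 genes in the planned fit, and leaving out any other library gave 0, with 2004 to 3704 genes at an unadjusted p under 0.05. The balance toward lower genes (32.4% higher) depended on the setting: 77.9% of calls were higher without sh-JMJD1C 1, 59.6% of 911 over protein-coding genes only, 51.8% of 114 with array weights and 50% of 2 after quantile normalization. The median log2 fold change over all genes was -0.16 in the planned fit, -0.38 for FPKM as deposited and -0.01 after quantile normalization. Changes are relative to the scaling used and are not centred on that median.

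Of the 34 genes, 13 passed the naming rule. Those higher in the sh-JMJD1C libraries were 6 histone genes, all on chromosome 6, and APOBEC3B-AS1. H2BC3 (ENSG00000276410, 26043277 to 26043657) had a log2 fold change of 5.51 (SE 0.67, adjusted p = 0.0450) in the limma fit. H2BC11 followed at 4.71 (12.8 ± 3.83 to 384 ± 209 scaled FPKM), H2BC14 at 4.42 (13.1 ± 7.47 to 259 ± 21.5), H2BC10 at 4.28 (61.0 ± 14.9 to 1253 ± 509), the H2A gene H2AC11 at 3.89 (27.0 ± 9.37 to 416 ± 177) and H2BC8 at 3.00 (24.98 ± 4.15 to 205 ± 38.7). Histone genes are near-identical copies of one another, so how reads were divided between them is uncertain. APOBEC3B-AS1, an antisense transcript of the APOBEC3B gene, had 0 reads in every control and 7, 3 and 4 reads in sh-JMJD1C 1 to 3, at least 7.05-fold higher.

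Of the 6 named genes that were lower, NIBAN1 (ENSG00000135842, chromosome 1, 184790724 to 184974550) had a log2 fold change of -3.52 (SE 0.42, adjusted p = 0.0444 in limma). CXCL2 (ENSG00000081041, chromosome 4, 74097035 to 74099293), a chemokine that attracts neutrophils, had 91 reads in the controls and 3 in the sh-JMJD1C libraries, a ratio of 20.1 (exact 95% interval 6.65 to 99.1). DNAJB9 (ENSG00000128590, chromosome 7, 108569568 to 108574850) had a log2 fold change of -2.59 (SE 0.31, adjusted p = 0.0444). The long non-coding RNA LINC00342 (ENSG00000232931, chromosome 2, 95807118 to 95816215) had 78 reads in the controls and 0 in the sh-JMJD1C libraries, at least 17.2-fold lower. SMYD3-AS1 had 24 reads against 0, at least 5.29-fold lower, and BCAN-AS1 went from 5.62 ± 1.14 to 0.381 ± 0.158 scaled FPKM. Without a stated strand, reads of the antisense genes cannot be told from those of overlapping genes on the other strand. In the planned fit, all 13 calls held without sh-JMJD1C 1 and were lost when any other single library was left out. On reads, H2BC3, H2BC11, H2BC14, H2BC10, H2AC11, H2BC8 and NIBAN1 passed whichever library was left out.

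On recovered reads, limma-voom called 656 of 11877 genes, 441 higher and 215 lower in the sh-JMJD1C libraries (67.2% higher). In 4102 genes (34.5%) the groups did not overlap, against 10% expected for a single gene by chance. Shifts shared by many genes of a library can move that share, and it was not computed for other splits. Scaling by library totals called 1195 genes with 26.0% higher, quantile normalization called 1020 with 52.3% higher, and the median log2 fold change over all genes was -0.08 with median-ratio scaling against -0.52 with library totals. With the trend over transcript length removed, 406 genes were called, 278 higher and 128 lower, and 306 of them were among the 656. With the GC trend removed as well, 802 were called, 54.1% of them higher, and 304 were among the 656. Leaving out control 1, control 3, sh-JMJD1C 2 or sh-JMJD1C 3 lowered the count to 35, 57, 31 or 122, and leaving out control 2 or sh-JMJD1C 1 raised it to 1237 or 2333.

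Outside the histone genes, 608 genes were called on reads, 394 of them higher, and the naming rule took 12 in each direction. TK1, the thymidine kinase of S phase, rose from 17.1 ± 5.70 to 198 ± 132 scaled RPM (log2 fold change 3.17, adjusted p = 0.0155 in limma-voom). IGFBP6, which binds insulin-like growth factors, rose from 3.29 ± 1.20 to 40.0 ± 17.1. TXNIP, the thioredoxin-interacting protein, rose from 2.71 ± 2.38 to 31.2 ± 3.97. The small GTPase RRAS, the chemerin gene RARRES2, the mitosis-associated PIMREG, the selenoprotein SELENOW, the mitochondrial ribosomal protein MRPL54, the complex I subunit NDUFB7, the neurogranin gene NRGN, the minor spliceosome protein SNRNP25 and the acyl-CoA thioesterase ACOT7 rose by log2 fold changes between 3.15 and 3.78. With the length trend removed, 9 of the 12 higher genes passed, and without both libraries numbered 1, 11 passed. All 12 lost their call when control 1, control 3 or sh-JMJD1C 2 alone was left out, with log2 fold changes between 2.43 (NRGN) and 4.40 (PIMREG) over all single removals. Their median longest transcript was 1793 nucleotides.

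SLFN5, an interferon-inducible member of the Schlafen family, fell from 146 ± 61.0 to 11.7 ± 1.77 scaled RPM (log2 fold change -3.51, adjusted p = 0.00542 in limma-voom) and passed whichever library was left out. MAP1B, a microtubule-associated protein, fell from 59.4 ± 13.1 to 6.43 ± 5.83. ETV5, an ETS transcription factor downstream of MAPK signalling, fell from 21.7 ± 8.02 to 2.02 ± 1.73. TRIM66, a chromatin-binding tripartite motif protein, fell by 4.09 on the log2 scale (adjusted p = 0.0149). CLGN, a chaperone of the endoplasmic reticulum, had 133 reads in the controls and 3 in the sh-JMJD1C libraries, a ratio of 29.3 (exact 95% interval 9.82 to 144), and DICER1-AS1 had 75 against 2, a ratio of 24.8 (6.63 to 209). The others that fell were NIBAN1 (-4.03), CXCL2 (-3.82), LINC00342, BCAN-AS1 (-3.47), FAM229A (-3.24) and the zinc finger gene ZNF37A (-3.23). With the length trend removed, 11 of the 12 lower genes passed, and without both libraries numbered 1, 4 passed. All but SLFN5 and NIBAN1 lost their call when control 1, sh-JMJD1C 2 or sh-JMJD1C 3 alone was left out.

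Among the 33 gene lists, 29 had at least 5 measured genes, and camera with the preset correlation called 9 of them in the planned fit and 8 on reads. With an estimated correlation it called 0 lists in either fit, with a smallest adjusted p of 0.378 and 0.469, and without both libraries numbered 1 it called 10 and 12 at the preset correlation. The replication-dependent histone list had an adjusted p of 1.58e-38 in the planned fit (adjusted p = 0.399 with an estimated correlation, fry p = 0.0021). Of these 61 genes, 6 passed over all genes, and 54 passed higher when adjusted over the list alone. On reads, 47 of 56 rose, and 53 rose adjusted over the list alone. The median on reads was 3.55, 11.7-fold, and 2.66 with the length trend removed, where 42 rose. Calls covered all 5 families: 12 of 14 H2A genes, 16 of 17 H2B genes, 6 of 8 H3 genes, 8 of 10 H4 genes and 5 of 7 H1 genes rose. The list took 0.338% ± 0.081 of reads in the controls and 2.71% ± 1.10 in the sh-JMJD1C libraries, beside the RN7SL and MALAT1 shares given above.

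**Figure D2:**
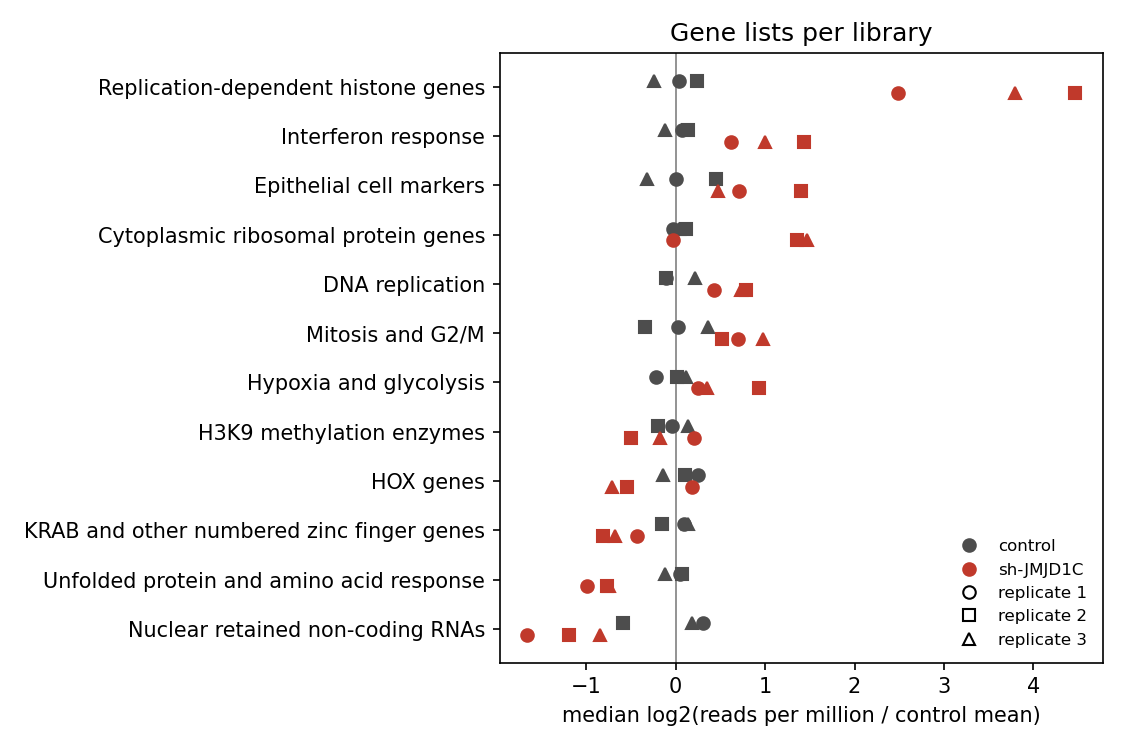
Median over the genes of a list of log2 RPM over the control mean (horizontal axis), for 12 lists (vertical axis) and each library (grey control, red sh-JMJD1C, shape by replicate number). Histone genes lie at 2.49, 4.47 and 3.79 in sh-JMJD1C 1 to 3, and ribosomal protein genes lie at -0.03, 1.36 and 1.47.

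The unfolded protein and amino acid response list was lower in the planned fit (36 genes, median -0.62, adjusted p = 5.30e-05 with camera, adjusted p = 0.378 with an estimated correlation, fry p = 0.000915). In that fit DNAJB9 alone passed over all genes, and 15 genes passed lower and 1 higher when adjusted over the list alone. On reads, 12 of 36 fell, 1 rose and 23 did not pass, and 15 fell and 1 rose adjusted over the list alone. HSPA5, the BiP chaperone, fell from 1904 ± 245 to 483 ± 211 scaled RPM (log2 fold change -2.07, adjusted p = 0.0226 in limma-voom). HSP90B1, the endoplasmic reticulum HSP90, fell from 794 ± 220 to 148 ± 54.0 (-2.46, adjusted p = 0.0155). The transcription factors CEBPG and DDIT3 fell by 3.10 and 2.60 on the log2 scale, and asparagine synthetase, ASNS, fell by 1.68. The member that rose was DDIT4 (1.87), an inhibitor of mTOR signalling that also belongs to the hypoxia list. The list median was -0.997, -0.769 and -0.743 in sh-JMJD1C 1 to 3, and with the length trend removed 9 genes fell, the named ones among them, and DDIT4 did not pass.

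**Figure D3:**
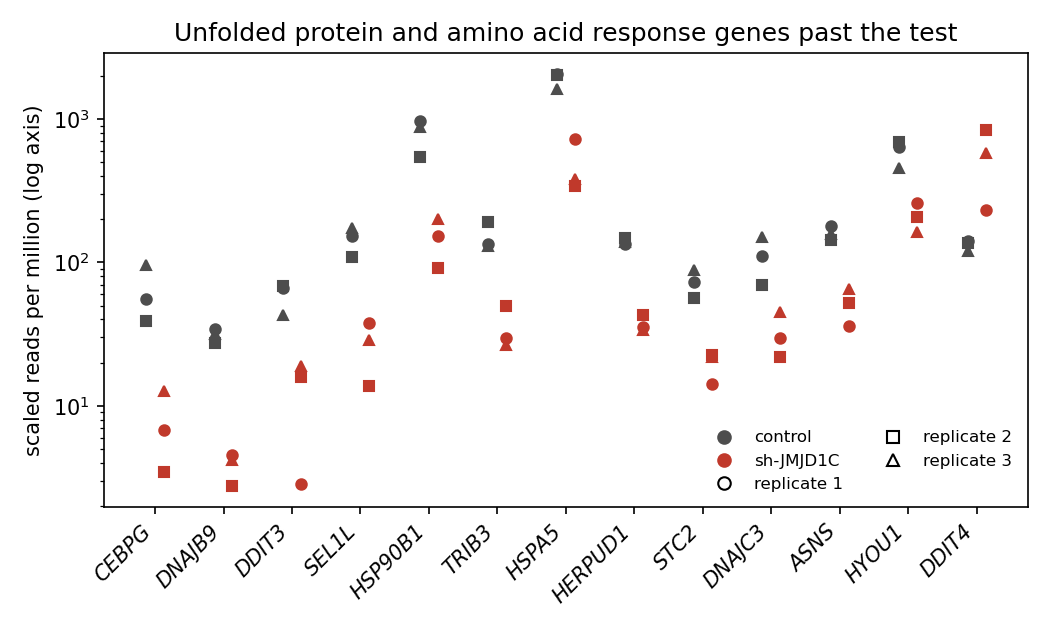
Scaled RPM (reads scaled to a common total) (vertical log axis) of the 13 genes of the unfolded protein and amino acid response list that passed on reads, in each library (grey control, red sh-JMJD1C, shape by replicate number). For 12 genes all sh-JMJD1C libraries lie below all controls, and for DDIT4 all lie above.

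Cell cycle lists were higher. The mitosis and G2/M list had a median of 0.64 over 51 genes in the planned fit (adjusted p = 6.83e-06 with camera, and adjusted p = 0.665 with an estimated correlation), where 0 passed over all genes and 19 passed higher adjusted over the list alone. On reads 13 of 52 rose and 39 did not pass, with 19 adjusted over the list alone. They included MYBL2, a transcription factor of cell cycle genes (2.50), the ubiquitin-conjugating enzyme UBE2C (2.44), the mitotic kinase PLK1 (2.39) and the kinesin KIF20A (2.28), all of which passed with the length trend removed, where 10 genes rose. The DNA replication list had a median of 0.60 over 44 genes (adjusted p = 6.83e-06, and adjusted p = 0.458 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone. On reads 5 of 44 rose and 39 did not pass, with 11 adjusted over the list alone, among them CCNE1, the cyclin of S phase entry (2.19), the helicase subunit MCM5 (1.43) and thymidylate synthase, TYMS (1.55). Once the length trend was removed 3 rose, CCNE1 and MCM5 among them, and TYMS did not pass (0.90, adjusted p = 0.158).

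The hypoxia and glycolysis list was higher in the planned fit (35 genes, median 0.50, adjusted p = 0.0172, and adjusted p = 0.745 with an estimated correlation), where 0 passed over all genes and 14 rose and 2 fell adjusted over the list alone. On reads 7 of 34 rose, 1 fell and 26 did not pass, 14 rose and 3 fell adjusted over the list alone, and the list had an adjusted p of 0.0712. Those that rose were DDIT4 and 6 enzymes of glycolysis: TPI1 (3.09), PGK1 (2.57), ENO1 (2.11), PGAM1 (1.97), PFKL (1.53) and PKM, pyruvate kinase, from 1028 ± 217 to 4840 ± 1647 scaled RPM, while VEGFA, the vascular growth factor, fell by 1.44. With the length trend removed 7 rose and 1 fell, but VEGFA (-0.54, adjusted p = 0.353), PGAM1 and DDIT4 did not pass. The interferon response list had a median of 0.67 over 24 genes (adjusted p = 0.00681, and adjusted p = 0.378 with an estimated correlation), with 0 passing over all genes and 2 adjusted over the list alone. On reads IFI35 (2.35) and OAS1 (1.75) rose, 19 of 21 did not pass, and 11 rose and 2 fell adjusted over the list alone. Neither IFI35 (1.55, adjusted p = 0.0543) nor OAS1 (1.44, adjusted p = 0.0529) passed with the length trend removed, though both stayed higher.

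Cytoplasmic ribosomal protein genes, a list that also holds some pseudogenes, had a median of 0.80 over 110 genes in the planned fit (adjusted p = 2.67e-06, and adjusted p = 0.745 with an estimated correlation), with 0 passing over all genes or adjusted over the list alone. Its camera test turned downward, with a median of 0.09 and an adjusted p of 0.854, under quantile normalization. On reads 2 of 90 rose, RPS9 and the pseudogene RPS10P2, neither of which passed with the length trend removed, where 0 rose and 1 fell. Library sh-JMJD1C 1 lay at the control level. KRAB and other numbered zinc finger genes were lower, with a median of -0.43 over 242 genes (adjusted p = 0.00113, and adjusted p = 0.665 with an estimated correlation) and 0 passing over all genes or adjusted over the list alone. On reads 6 of 251 fell, among them ZNF621 (-3.07) and ZNF664 (-2.14), ZNF511 rose (2.99), and 2 fell adjusted over the list alone. Of these 7 genes, ZNF621 and ZNF664 passed with the length trend removed, where 2 fell and 0 rose. Epithelial cell markers had a median of 0.78 over 9 genes (adjusted p = 0.00481, and adjusted p = 0.665 with an estimated correlation), with 0 passing over all genes and 2 adjusted over the list alone. On reads the keratins KRT8, from 371 ± 114 to 3078 ± 1626 scaled RPM, and KRT18 (1.87) rose, 7 of 9 did not pass, and 3 rose adjusted over the list alone. KRT8 passed with the length trend removed and KRT18 did not (adjusted p = 0.0607).

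The other lists were not called in the planned fit. Nuclear retained non-coding RNAs had a median of -0.85 (adjusted p = 0.164), and on reads 5 of 14 fell and 2 rose, with 6 and 2 adjusted over the list alone. Of these, MALAT1 fell from 15890 ± 5121 to 2045 ± 792 scaled RPM (log2 fold change -3.01, adjusted p = 0.0109 in limma-voom), NEAT1, the scaffold of paraspeckles, fell by 1.96, and the small Cajal body RNAs SCARNA5 and SCARNA6 rose. With the length trend removed MALAT1 alone passed (-2.25, adjusted p = 0.0212), and NEAT1 stood at -0.82 (adjusted p = 0.191). H3K9 methylation enzymes, the class of JMJD1C's relatives KDM3A and KDM3B, had a median of -0.22 over 23 genes (adjusted p = 0.697). On reads MPHOSPH8, a reader of methylated H3K9, fell by 1.75. With the length trend removed it kept most of its fold (-1.53) but did not pass (adjusted p = 0.0656). Medians were -0.46 for the m6A machinery (adjusted p = 0.0776), -0.44 for HOX genes (0.161), 0.27 for heat shock and chaperones (0.164), 0.18 for apoptosis regulators (0.329), -0.45 for fatty acid synthesis (0.380) and -0.41 for TGF-beta and BMP signalling (0.512). Mitochondrially encoded genes had a median of -0.65 (0.512), the JAK-STAT pathway -0.31 (0.528), p53 target genes -0.35 (0.528), the DNA damage response -0.26 (0.637), extracellular matrix and mesenchymal genes -0.22 (0.671) and receptor tyrosine kinase and MAPK signalling -0.26 (0.671). On reads the mitochondrial list had a median of -0.62 (adjusted p = 0.319) and was called once the length trend was removed (median -1.50, adjusted p = 0.00202, and adjusted p = 0.826 with an estimated correlation). Its medians per library were 1.22, -1.42 and -1.35 in sh-JMJD1C 1 to 3 and 0.76, 0.48 and -1.25 in control 1 to 3. Medians were -0.13 for Wnt signalling (0.671), -0.28 for RNA polymerase II pause and elongation (0.687), -0.39 for cholesterol synthesis (0.697), -0.04 for immediate early genes (0.801), -0.06 for NF-kB and inflammatory cytokines (0.940) and -0.15 for neural stem and glial genes (0.940). Too few genes were measured in the lists of haematopoietic markers (0), clustered protocadherins (1), neuron and oligodendrocyte markers (2) and endothelial markers (3).

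Fold changes on reads also went with transcript length and with GC content. Across protein-coding genes outside the histones, the rank correlations were -0.473 and 0.576. Genes and lists given above with the length trend removed were not corrected for GC content as well. Of single genes, JMJD1C alone is given with both trends removed. Among protein-coding genes outside the histones, the median log2 fold change was 1.23 for 362 genes with a longest transcript of 600 to 1200 nucleotides, 0.39 for 2003 genes of 2000 to 3000 and -0.55 for 2319 genes of 5000 to 8000.

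**Figure D4:**
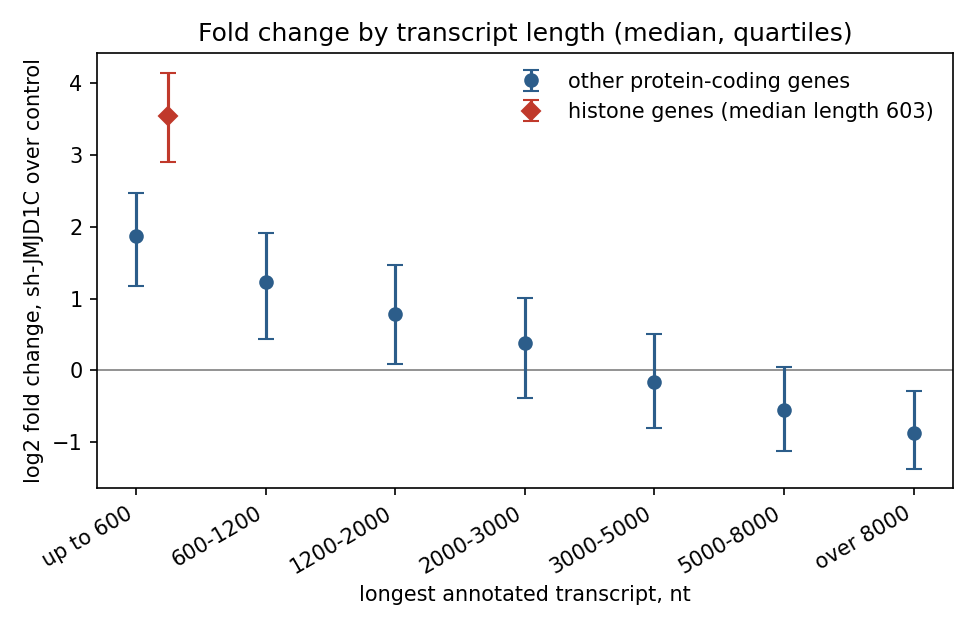
Log2 fold change on reads (vertical axis, median with quartiles) by longest annotated transcript in nucleotides (horizontal axis, classes), for protein-coding genes outside the histones (blue) and for the 56 histone genes (red). Medians run from 1.87 to -0.87 from the shortest to the longest class, and the histone median of 3.55 lies above all of them.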

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

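The fits on reads and the removal of both libraries numbered 1 were chosen after seeing the data. The planned limma count of 34 genes became 84 with a pseudocount of 0.1, 79 for FPKM as deposited, 114 with array weights and 911 over protein-coding genes only, where fewer genes were tested. It became 2 with a mean FPKM of at least 2 and 2 after quantile normalization. It became 0 with a pseudocount of 1, without a filter, without trend and without both libraries numbered 1, while 3585, 3821, 3465 and 4206 genes had an unadjusted p under 0.05. Leaving out each library gave 0 to 488. JMJD1C passed over protein-coding genes only (log2 fold change -1.82), stood between -2.38 and -1.44 over the alternatives run, and did not pass in the others.

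The count of 656 on reads became 1195 with library totals, 1020 after quantile normalization, 1051 over protein-coding genes only, 406 with the length trend removed, 802 with length and GC trends removed and 1007 without both libraries numbered 1. Leaving out each library gave 31 to 2333. The JMJD1C level on recovered reads was -1.20 (adjusted p = 0.0574) with length and GC trends removed and -2.93 to -1.96 with each library left out. With an estimated inter-gene correlation 0 lists were called in either fit. The ribosomal protein list reversed after quantile normalization (median 0.09). The cause was not tested for any of these changes except the fewer genes or libraries named.

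With the replicate number as a block, the planned limma count was 0 (4407 genes at an unadjusted p under 0.05), the count on reads was 4260, and 3364 with the length trend removed as well. Deviations of libraries with the same number correlated at 0.009, 0.140 and 0.220 on FPKM and 0.023, 0.375 and 0.480 on reads. Control 1 correlated best with sh-JMJD1C 3, at 0.027 on FPKM and 0.085 on reads. The other controls each correlated best with the sh-JMJD1C library of their own number, on both scales. Whether the numbers pair the libraries therefore stays open, and the fits without a block were kept as the main ones.

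No named gene changed direction, but the naming rule took large folds without overlap between the groups, which left little room for a reversal. Of 216 comparisons for the 13 planned genes, 60 kept their side of the threshold and 156 lost the call. Of 480 for 31 genes on reads, 364 kept it and 116 lost it. Of 492 list comparisons in the planned fit, 472 kept their side, 8 lost and 11 gained a call, and of 462 on reads, 430 kept their side, 7 lost and 25 gained a call. The histone median was above 0 under every setting run, 2.44 to 3.89 in the planned fit and 2.46 to 4.15 on reads. Depth limits genes of few reads, with 3 reads worth 5.51 RPM in control 1.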

Other observations

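The cytoplasmic mRNA and poly(A) tests of the histone genes and the length test of JMJD1C were chosen after their results were seen, as were all fits on reads, and the other tests were set before. Outside the lists called in the planned fit, single genes of several pathways passed on reads with limma-voom. Of receptor tyrosine kinase and MAPK genes, the kinase TYRO3 (log2 fold change 2.22), the GTPase HRAS (1.94) and the kinase AKT1 (1.46) rose, while ETV5 (-3.53) fell. Of apoptosis regulators, the initiator caspase CASP9 (1.99) and the effector BAK1 (2.36) rose and the caspase inhibitor XIAP (-2.12) fell. Of NF-kB and inflammatory genes, the inhibitor NFKBIA (1.58) rose and NFKBIZ (-2.31) fell with CXCL2. H2AX, the histone variant marked at DNA breaks (2.61), the p53 target FDXR (2.17) and ID3, a target of BMP signals (2.43), also rose. Of heat shock and chaperone genes, the small heat shock protein HSPB1 (2.09) and FKBP4 (1.67) rose. The Wnt regulator APC (-1.76) and the laminin LAMB1 (-1.65) fell. With the length trend removed, TYRO3, AKT1, ETV5, CASP9, NFKBIZ, CXCL2, H2AX and FKBP4 (1.78) still passed. HRAS, BAK1, XIAP, NFKBIA, FDXR, HSPB1, ID3, APC and LAMB1 did not. Of these, BAK1 (1.95, adjusted p = 0.0626) and FDXR (1.89, adjusted p = 0.0529) kept most of their fold. Smaller folds were left for XIAP (-1.39), HSPB1 (1.36), NFKBIA (0.89) and APC (-0.93).

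Short RNA genes had positive medians that were smaller once the length trend was removed. On reads, 37 genes of miscellaneous small RNA had a median log2 fold change of 2.57 (1.47 with the length trend removed, 9 genes called higher), 20 snRNA genes 2.41 (1.10, 3 called) and 45 snoRNA genes 1.82 (0.45, 1 called), and no test was run on these classes as sets. By contrast, 167 lincRNA genes had a median of -0.80 and 16 sense intronic genes -1.63. Among protein-coding genes outside the histones, medians went from 1.87 for 21 genes with a longest transcript of up to 600 nucleotides to -0.87 for 986 genes over 8000.

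The histone rise is larger than that of other short transcripts. The histone median of 3.55 exceeded that of 1910 other protein-coding genes (0.80, 75th percentile 1.495) by 2.75. Those genes lay in the length range of most histone genes but were not matched to the histone median length of 603 nucleotides. Nearer that length the excess was smaller. The median was 1.87 for 21 genes of up to 600 nucleotides and 1.23 for 362 of 600 to 1200. Both lay below the lower quartile of the histone genes (2.90), which argues against length alone. The histone median exceeded that of 79 protein-coding ribosomal protein genes (0.93) by 2.61, which argues against more cytoplasmic mRNA as the whole cause. The sh-JMJD1C libraries may hold more RNA without a poly(A) tail, since 71 snRNA, snoRNA and scaRNA genes had a median of 1.94. That median was 0.62 with the length trend removed. These RNA classes took 0.722%, 0.809% and 0.362% of reads in control 1 to 3 and 0.965%, 3.34% and 3.26% in sh-JMJD1C 1 to 3. In sh-JMJD1C 1 their share was thus near the controls. The histone list took 1.51% of reads in that library, against 0.268%, 0.426% and 0.318% in control 1 to 3. The design text gives depletion of ribosomal RNA, and whether a tail affected recovery was not tested. A larger share of cells in S phase may also contribute, since the DNA replication list kept a median of 0.625 with the length trend removed (adjusted p = 0.000132, and adjusted p = 0.334 with an estimated correlation). The mitosis and G2/M list kept a similar median of 0.623 (camera adjusted p = 3.98e-05, and adjusted p = 0.701 with an estimated correlation). The rise was thus not particular to S phase genes. More RNA without a tail and a larger share in S phase both stay open. An effect of the knockdown itself on histone transcripts also stays open and was not tested.

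The lower level of long transcripts went with transcript length at a rank correlation of -0.473 across 10155 genes, which are not independent replicates. Fold change also went with GC content, at a rank correlation of 0.576, larger in size than that with length. The tables argue against GC content as the whole source of the length trend, since the correlation with length was -0.385 after the GC trend was removed. Whether length accounts for the association with GC content was not tested. Less unspliced RNA of long genes could contribute: the partial rank correlation with genomic span given transcript length was -0.179, against -0.329 for length given span. The trend could also belong to single libraries, since the slopes per doubling of length were 0.308, 0.180 and 0.406 in control 1 to 3 and 0.035, -0.535 and -0.395 in sh-JMJD1C 1 to 3, and their widest range within a group was 0.957 of the difference between group means. RNA fragmentation and an effect of the knockdown were not tested. The degree of nuclear enrichment was not measured. On reads 5 of 14 nuclear retained RNAs fell, MALAT1 among them, and 2 rose, though the list was not called. RN7SL shares were highest in sh-JMJD1C 2 and 3. A difference in nuclear enrichment between the groups therefore stays open, for this trend and for the changes of genes and lists.

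The length trend does not account for JMJD1C, whose longest transcript has 8666 nucleotides, as the whole cause: its log2 fold change was -1.752 (SE 0.42, adjusted p = 0.0463 in limma-voom) with the trend removed, against -2.49 before. With the GC trend removed as well, the JMJD1C level on recovered reads was -1.20 (SE 0.33, adjusted p = 0.0574): the fold was smaller and the call ended, so a share of the fall that goes with both trends stays open.

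The 6 libraries allow 10 splits into equal groups, which are too few for a share under 0.05. The real split gave 34 genes in the planned fit, where 1 of the 10 splits gave as many and the highest other gave 5. On reads it gave 656, where 1 of the 10 splits gave as many and the highest other gave 0. For gene lists it gave 9, where 2 of the 10 splits gave as many: control 1, control 2 and sh-JMJD1C 1 against the rest gave 11.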
